A study of Homo sapiens with 8 samples.

How the data were processed

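RNA of HCT116 cells (WT) and of the derived KO1 cells was sequenced in 4 libraries per group, 8 in all. Per the labels' protocols, cells were grown with 10% fetal bovine serum, and poly(A) RNA was selected from 500 ng of total RNA, fragmented to a median of 150 bp, converted to cDNA with random primers, amplified with 7 cycles of PCR and sequenced in pairs of 75-bp reads, all 8 libraries multiplexed together. The kit named there does not mark the strand, so reads of overlapping antisense genes could not be told apart. Per the submitters' processing notes, which give tools without their roles, TopHat2 2.0.9, HTSeq (version not given in the sources used here), edgeR 3.2.4 and the hg19 genome were used. The gene annotation, the overlap mode and the strand setting of the counting are not given in the sources used here.

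The authors deposited whole-number counts per gene symbol for each library, not normalized, as HTSeq writes them. Each file had 22224 rows that name a gene or transcript, 19 of them with a transcript identifier in place of a symbol, and 5 further rows that name none. The latter were kept out of library sizes and tests. They held a mean of 13.7% (WT) and 14.0% (KO1) of the alignments counted as outside genes, 1.97% and 1.81% as ambiguous, and 25.5% and 24.9% as not uniquely aligned. The ambiguous and not unique shares differed between the groups (exact permutation test of 4 against 4, two-sided, p = 0.0286 each, the smallest possible). A difference in the share outside genes did not pass that test (exact permutation p = 0.200). The 10 rows with the most counts took 6.48% of gene counts in WT and 5.52% in KO1 (exact permutation p = 0.0286). HLA-B, TAP1, PSMB8 and TNF, of the MHC region, had at most 1 count in any library. How reads of that region were aligned is not given in the sources used here, so these counts do not show that the genes were silent. The mitochondrially encoded transcripts of the quality list were not found among the symbols and are not analysed here. Because not unique alignments were not counted, genes with near-identical copies may be undercounted.

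From the deposited counts, library sizes were scaled by edgeR's TMM factors (0.986 to 1.01), and values are given as CPM on that scale. Genes were kept by filterByExpr with a minimum count of 10 and a minimum total of 15, which left 13745, and 3610 rows had 0 counts in each library. The 2 groups were compared with edgeR 4.0.16 by the quasi-likelihood F test (glmQLFit and glmQLFTest, two-sided) in R 4.3.3, with Benjamini-Hochberg adjustment over the tested genes and a threshold of 0.05. The standard error of a log2 fold change was its absolute value divided by the square root of F. For genes near 0 in one group this value understates the uncertainty. Gene lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01 and adjusted over 26 lists. A family of 3 lists, on RNA quality and fibroblasts, was adjusted on its own. A list needed 5 tested members, or 3 for the metastasis list, so 4 of the 33 lists fixed were not tested. The lists, the design, the naming rule and the alternatives below, except where said, were fixed before the data were examined.

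The named genes are PPARD, the 12 largest changes in each direction among genes past the threshold with an average log2 CPM of at least 3 (edgeR's average) and no overlap between the groups, up to 4 members of each pathway list with the smallest p, 2 of each quality or cell type list, and every member of the metastasis list. Symbols of uncharacterised, micro and small nucleolar RNAs were left out of the largest changes. Some genes that the rule names, and a test that rested on 1 further gene, are not reported here. Single values were compared by exact permutation tests. Intervals of count ratios are exact binomial 95% intervals, and the floor for a group at 0 was 3 counts per library, which was 0.154 to 0.192 CPM.

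Replicates were compared before they were averaged. Each of the 12 pairs within a group differed by more than sampling noise, with a chi-square per degree of freedom between 1.39 and 3.39 over genes with a total of at least 50 counts. No 2 libraries were therefore merged as copies of 1 library. Library preparation alone can give such an excess, so it does not show that the libraries came from separate cultures.

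The tests were tried on simulated counts drawn from the means, library sizes and dispersions of the real libraries, for the comparison of KO1 against WT. Of 50 genes changed by 1.2-fold, 68% were recovered, of 50 by 1.5-fold 88%, of 50 by 2-fold 96% and of 50 by 4-fold 100%, among 13653 genes tested. Of the 188 genes called, 12 (6.38%) had not been changed. Far fewer genes were changed in this trial than were called in the real data. Its shares of recovered genes and false calls therefore need not hold there. Camera called the 1 list that was shifted and 0 of 28 others, and the running median placed 58 of 60 shifted neighbours in a run and 0 of the other genes. Genes were drawn independently of each other, while the correlation estimated within the real lists reached 0.30 (unfolded protein and ATF4 response). The trial therefore does not show how often camera's preset correlation gives false calls for correlated genes. The planted run of neighbours was 2-fold lower and lay inside a chromosome. It does not show how the running median handles weaker runs or runs at chromosome ends.

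The alternatives tried were RLE, upper-quartile and no scaling factors, DESeq2 1.42.0, edgeR's exact test, limma-voom, no low-count filter, a filter of CPM of at least 1 in 4 libraries, the replicate number as a block, each library left out in turn, camera with an estimated correlation, and limma's fry. The RefSeq gene table of GRCh38.p14, another build than that of the files, was used only for gene names and for which genes neighbour each other, and matched 13286 of the tested genes (96.7%). No coordinates are given for that reason. GC content and transcript length were taken from GENCODE v29 transcripts.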

Results

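The data were gene counts from poly(A)-selected RNA of HCT116 cells, an established human colon cancer line, in 2 groups. The WT group was the parental line, and the KO1 group was HCT116 with a genetic knockout of PPARD, with 4 libraries in each group. PPARD encodes the nuclear receptor PPAR delta, a lipid-sensing transcription factor. Each library held between 15738864 and 19799375 counts assigned to genes, and a difference in this depth between the groups did not pass an exact permutation test (two-sided, p = 1). The comparison asked how the transcriptome of the colon cancer cells differed when PPARD was disrupted. The labels do not say that the 4 libraries of a group came from separate cultures. The p-values therefore measure the spread between these libraries, which may be technical, and only 1 knockout line was profiled.

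PPARD mRNA was lower in each KO1 library than in any WT library, but it was not absent. It reached 49.9 ± 2.41 CPM (counts scaled to the size of the library) in WT and 24.1 ± 0.80 in KO1 (SD, n = 4 each), so that KO1 held 48.3% of the WT level. The 4 WT libraries had 52.7, 50.9, 47.1 and 49.1 CPM, from 1028, 942, 800 and 769 counts. The 4 KO1 libraries had 23.7, 23.9, 23.5 and 25.3 CPM, from 401, 457, 413 and 466 counts. The log2 fold change, KO1 minus WT, was -1.05 with a standard error of 0.0465 (edgeR adjusted p = 5.75e-25). An exact two-sided permutation test of the 8 CPM values gave p = 0.0286, the smallest that 4 libraries against 4 can give. Counts summed over a gene do not show which exons the reads came from, so the remaining counts do not tell whether the PPARD transcript was intact. Of the 19 tested genes next to PPARD on 6p21, 6 were higher, 6 were lower and 7 did not pass the test, both over all genes and adjusted over the list alone. BRPF3 (log2 fold change -0.39) and FKBP5 (-0.31) were among the lower ones, and the list did not pass the test for a shift (camera adjusted p = 0.804).

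**Figure D1:**
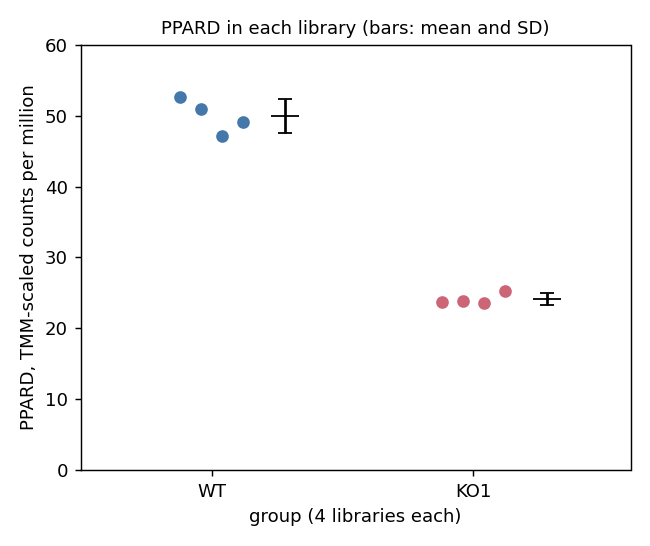
PPARD in TMM-scaled CPM (y axis, from 0) in the 4 WT and the 4 KO1 libraries (points), with the mean and SD of each group as a bar beside the points. The KO1 libraries lie between 23.5 and 25.3, below the WT libraries at 47.1 to 52.7.

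The largest losses in KO1 were of genes for ubiquitin, cell contacts, the cytoskeleton and the matrix. UBB, one of the genes that encode ubiquitin, fell from 289 ± 3.99 CPM in WT to 0.179 ± 0.111 in KO1 (SD, n = 4 each), which was 1 to 6 counts per KO1 library. GJA1, which encodes the gap junction protein connexin 43, fell from 136 ± 4.35 to 0.156 ± 0.0907 CPM, and COL6A3, a collagen VI chain, from 50.6 ± 1.38 to 0.461 ± 0.187 CPM. VIM, the mesenchymal intermediate filament vimentin, was the most abundant of the 12 largest losses and fell from 788 ± 9.72 to 24.2 ± 1.48 CPM (SD, n = 4 each). SPARC, a secreted matrix glycoprotein, fell from 144 ± 8.75 to 4.83 ± 0.765 CPM, and CYP51A1, the lanosterol demethylase of cholesterol synthesis, from 330.1 ± 12.8 to 28.8 ± 1.01 CPM. Among the 12 were also MAGEB1 (log2 fold change -6.97), HCLS1 (-5.89), VAT1L (-5.75), the imprinted non-coding RNA H19 (-4.52) and the phospholipase gene PLA2G16 (-3.96). UBB has near relatives, and MAGEB1 belongs to a multigene family, so the counts of both are uncertain to the extent that reads were shared between copies.

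The largest gains were smaller on the log2 scale than the largest losses. SYTL5, a synaptotagmin-like Rab effector, rose from 2.63 ± 0.565 CPM in WT to 49.7 ± 1.75 in KO1 (SD, n = 4 each). TNC, the matrix protein tenascin C, rose from 1.6 ± 0.0866 to 21.5 ± 1.38 CPM, and EMP1, an epithelial membrane protein, from 12.8 ± 0.708 to 104 ± 5.12 CPM. F3, which encodes tissue factor, the starter of blood clotting, rose from 28.5 ± 1.26 to 197 ± 2.26 CPM. ANO1, a calcium-activated chloride channel, rose from 72.9 ± 2.03 to 399 ± 5.85 CPM (SD, n = 4 each). Among the 12 largest gains were also C1orf116 (log2 fold change 3.90), FXYD3 (2.44), the non-coding RNA UCA1 (2.43), the laminin chain gene LAMA3 (2.39), the actin-bundling gene LCP1 (2.30) and the metallothionein MT1E (2.15). MT1E has close paralogs, which makes its count uncertain. Each of the 24 genes with the largest changes passed the edgeR quasi-likelihood test, with adjusted p-values from 3.25e-61 for VIM to 5.23e-10 for MT1E, and had 4 KO1 values that did not overlap the 4 WT values.

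**Figure D2:**
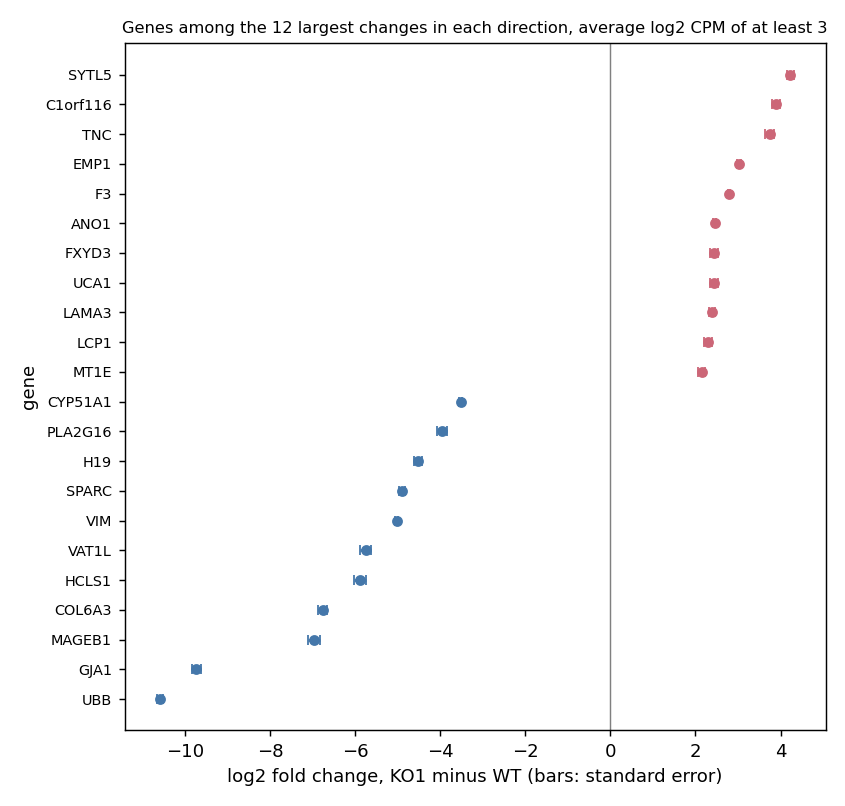
Log2 fold change, KO1 minus WT (x axis), of 11 of the 12 genes with the largest gain and 11 of the 12 with the largest loss among genes with an average log2 CPM of at least 3 (y axis), with standard errors as bars. Gains reach 4.23 (SYTL5) and losses reach -10.59 (UBB).

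Across the transcriptome, 8650 of 13745 tested genes (62.9%) differed between KO1 and WT (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), 4369 of them higher and 4281 lower in KO1. Many of these differences were small, since 4208 were below 1.2-fold and the median absolute log2 fold change of the changed genes was 0.27. At least 2-fold changes were found for 655 genes, of which 162 were higher and 493 lower, and at least 4-fold changes for 213 genes, 31 higher and 182 lower. The biological coefficient of variation between libraries of a group was 2.46%.

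The fatty acid genes through which PPAR delta is best known did not move together. Among 17 tested canonical PPARD target genes, 8 were higher in KO1, 6 were lower and 3 did not pass the test, with the same counts adjusted over the list alone. CPT1A, the carnitine acyltransferase that admits fatty acids to mitochondria, rose from 185 ± 3.28 to 265 ± 2.83 CPM (SD, n = 4 each). PDK4, the kinase that restrains pyruvate oxidation, fell from 6.27 ± 0.283 to 2.52 ± 0.176 CPM. ACADVL (log2 fold change 0.29) and ECH1 (0.34), both of fatty acid oxidation, rose slightly. ANGPTL4 (0.04) and PLIN2 (-0.01), further standard targets outside the naming rule that were picked after their values were seen, did not pass the test. The list as a whole did not pass camera's test (adjusted p = 0.615), while fry, which does not compare a list with other genes, called it up (adjusted p = 0.00618). Its median log2 fold change was 0.04, its mean was -0.04, and the test pointed up.

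Among 24 tested genes of fatty acid beta-oxidation, 9 were higher, 9 lower and 6 not called, with the same counts adjusted over the list alone (camera adjusted p = 0.992). Next to CPT1A and ACADVL, which were higher, the medium-chain dehydrogenase ACADM (-0.31) and the enoyl-CoA isomerase PECI (-0.43) were lower. Of 17 genes of fatty acid synthesis and desaturation, 5 were higher, 6 lower and 6 not called, also adjusted over the list alone (camera adjusted p = 0.469). ACSL5, an acyl-CoA synthetase, fell from 50.2 ± 2.29 to 9.93 ± 0.981 CPM, and fatty acid synthase, FASN, from 2186 ± 41.7 to 1466 ± 18.6 CPM (SD, n = 4 each). ACSL1 (log2 fold change 0.48) rose and malic enzyme ME1 (-0.39) fell. The median of this list was 0.01, while its mean, -0.12, and its test pointed down. In the list of PPAR and RXR receptors and their co-regulators, 5 of 13 tested genes were higher, 5 lower and 3 not called, likewise adjusted over the list alone (camera adjusted p = 0.804). NRIP1, a nuclear receptor corepressor, fell from 3.39 ± 0.396 to 0.25 ± 0.149 CPM. PPARA was lower (-0.44), and NCOR1 (0.31) and NCOA1 (0.29) were higher. The median of the receptor list was 0.02, while its mean, -0.28, and its test pointed down.

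Cholesterol synthesis genes were lower on balance. Of 25 tested genes of cholesterol synthesis and uptake, 15 were lower, 7 higher and 3 not called, with the same counts adjusted over the list alone (camera adjusted p = 4.06e-04). Beside CYP51A1, mevalonate kinase MVK fell from 71.2 ± 1.45 to 39.3 ± 1.19 CPM (SD, n = 4 each), and HMGCS1 (log2 fold change -0.41) fell less. CYP51A1 (-3.52) was the only member changed at least 2-fold, while the median of the list was -0.12 and its mean -0.22. How far the call rests on CYP51A1 was not tested. The call on this list was lost when the correlation between its genes was estimated (adjusted p = 0.345 with an estimated correlation).

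Genes of sugar breakdown and of the response to low oxygen were lower, and respiratory chain genes were slightly higher. In glycolysis, 14 of 21 tested genes were lower, 2 higher and 5 not called, also adjusted over the list alone (camera adjusted p = 0.00199; adjusted p = 0.0680 with an estimated correlation). The glucose transporter gene SLC2A1 fell from 201 ± 9.96 to 105 ± 1.89 CPM (SD, n = 4 each), and ALDOC (-0.51), HK2 (-0.48) and ENO1 (-0.29) fell by smaller log2 fold changes. Of 20 hypoxia-response genes, 16 were lower and 4 not called, over all genes tested and adjusted over the list alone (camera adjusted p = 1.04e-05; adjusted p = 0.0938 with an estimated correlation). NDRG1, a stress gene induced in hypoxia, fell from 368 ± 9.52 to 179 ± 11.2 CPM, and the collagen hydroxylase P4HA1 (-0.74), the histone demethylase KDM3A (-0.59) and the mitophagy receptor BNIP3L (-0.45) also fell. In the nuclear-encoded oxidative phosphorylation list, 25 of 40 genes were higher, 2 lower and 13 not called, with the same counts adjusted over the list alone (camera adjusted p = 0.00151; adjusted p = 0.180 with an estimated correlation). The median change of this list was 0.15 on the log2 scale, and its examples NDUFA9 (0.50), CYC1 (0.46), SDHD (0.45) and NDUFB8 (0.29) lay above that.

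The 5 genes that published work on these cells tied to metastasis, GJA1, VIM, SPARC, STC1 and SNCG, all fell (camera adjusted p = 4.88e-84; adjusted p = 1.18e-04 with an estimated correlation). SNCG, gamma-synuclein, fell from 20.7 ± 1.38 to 6.36 ± 0.590 CPM and STC1, the secreted hormone stanniocalcin 1, from 4.86 ± 0.669 to 1.18 ± 0.208 CPM (SD, n = 4 each). All 5 of 5 were also lower adjusted over the list alone. That list was probably chosen on these same libraries, so it is not independent evidence of its direction. Its STC1 is also in the hypoxia list above, and its VIM and SPARC are in the mesenchymal list below. The calls on those lists are not independent evidence to the extent that they rest on these genes.

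Mesenchymal and matrix genes moved in both directions. Of 23 tested, 12 were lower, 8 higher and 3 not called, with the same counts adjusted over the list alone (camera adjusted p = 4.96e-04). VIM and SPARC, described above, were the largest losses, while TNC and the caveolae protein gene CAV1 rose, the latter from 133 ± 4.61 to 267 ± 2.92 CPM (SD, n = 4 each). Both VIM and SPARC are also in the metastasis list, so the downward call rests at least in part on genes probably chosen on these libraries. VIM (-5.02) and SPARC (-4.89) lay far below the mean of the list, -0.36, and its median, -0.26. The list was not tested without them, so how far its call rests on them is not known. The call on this list was lost with an estimated correlation and without the low-count filter (adjusted p = 0.0938 with an estimated correlation; camera adjusted p = 0.172 without the filter). Markers of fibroblasts moved with the same groups: 5 of 11 could be tested and all 5 were lower in KO1, also adjusted over the list alone, among them COL6A3 and COL3A1 (-4.41). The fibroblast list was tested apart from the pathways (camera adjusted p = 3.85e-13; adjusted p = 8.33e-04 with an estimated correlation). COL1A2 and DCN, other abundant fibroblast transcripts, were near 0 in WT, at 0.0135 ± 0.0270 and 0.0454 ± 0.0568 CPM (SD, n = 4 each), while COL1A1 was 76.7 ± 4.32 CPM in WT and 51.8 ± 3.49 in KO1.

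Epithelial adhesion and junction genes rose more often than they fell, and whether the list shifted depended on the setting. Of 29 tested, 16 were higher, 8 lower and 5 not called, and adjusted over the list alone 17 were higher and 8 lower (camera adjusted p = 0.0662). E-cadherin, CDH1, rose from 53.9 ± 2.32 to 97.8 ± 5.14 CPM and keratin 8, KRT8, from 625 ± 20.9 to 1025 ± 11.5 CPM (SD, n = 4 each), whereas the claudin CLDN3 (-1.61) and desmocollin DSC2 (-0.72) fell. The list passed the threshold without scaling factors (camera adjusted p = 0.0476), without the low-count filter (0.0394), with the replicate block (0.0338), with fry (3.51e-04) and without WT replicate 2 (0.0427), while its adjusted p was 0.482 with an estimated correlation. Among 17 tested Wnt/beta-catenin targets, 10 were lower, 4 higher and 3 not called, with the same counts adjusted over the list alone (camera adjusted p = 0.0505). SOX4 (-1.09), MYC (-0.77) and SOX9 (-0.34), which encode transcription factors, fell, and RNF43, a ubiquitin ligase that restrains Wnt signalling, rose (1.18). The Wnt list lay just below the threshold, at camera adjusted p-values of 0.0385 to 0.0465, without WT replicate 1, 2 or 4 or without KO1 replicate 1 or 4. It also passed with the replicate block (0.0338) and fry (2.17e-05), while its adjusted p was 0.283 with an estimated correlation.

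Inflammatory genes were lower. In the list of NF-kappaB and cytokine genes, 15 of 20 tested were lower, 2 higher and 3 not called, over all genes and adjusted over the list alone (camera adjusted p = 5.03e-07; adjusted p = 0.0541 with an estimated correlation). IL8, the neutrophil chemokine, fell from 54.4 ± 3.92 to 5.87 ± 0.606 CPM, and the adhesion receptor gene ICAM1 from 10.6 ± 0.845 to 0.777 ± 0.10 CPM (SD, n = 4 each). TNFAIP3, a feedback inhibitor of NF-kappaB, fell from 124 ± 4.98 to 22.6 ± 1.2 CPM, while IL18 rose from 20.2 ± 0.597 to 79.4 ± 1.73 CPM. Interferon-stimulated genes split, with 9 of 28 higher, 7 lower and 12 not called, also adjusted over the list alone (camera adjusted p = 0.811). BST2, which tethers virus particles to the cell, fell strongly (log2 fold change -3.69), as did the exonuclease gene ISG20 (-1.02), while ISG15 (0.63) rose. The median of this list was 0.07 and its test pointed up, while its mean was -0.16. Of 17 class I antigen presentation genes only 7 could be tested, 2 higher, 4 lower and 1 not called, with the same counts adjusted over the list alone (camera adjusted p = 0.811). B2M (-0.23), CALR (-0.12) and PDIA3 (-0.13) were lower and PSMB10 was higher (0.38). The median of the 7 was -0.12 and the test pointed down, while the mean was 0.01. HLA-B and TAP1, also of this list, had at most 1 count in any library of either group and could not be compared. Alignments that were not unique were not counted, so these counts do not show that the genes were silent.

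The list of EGFR ligands and MAPK feedback genes moved in both directions and shifted down. Among 24 tested members, 12 were lower, 7 higher and 5 not called, also adjusted over the list alone (camera adjusted p = 2.18e-08; adjusted p = 0.0541 with an estimated correlation). DUSP6, a phosphatase that switches off ERK, fell from 319 ± 8.46 to 125 ± 2.88 CPM and EREG, the ligand epiregulin, from 135 ± 2.06 to 73.8 ± 2.15 CPM (SD, n = 4 each). EGR1 (-1.23) and SPRY4 (-0.75) also fell. The median of the list was only -0.07, and its ETV5 (-3.35), named after its values were seen, lies in a stretch of chromosome 3 whose genes were mostly lower. Immediate early genes, which respond to handling as well as to signalling and include EGR1, moved with the same groups: 12 of 13 were lower and 1 higher, also adjusted over the list alone (camera adjusted p = 1.38e-11; adjusted p = 0.0118 with an estimated correlation). JUN, for example, fell from 139 ± 4.28 to 79.3 ± 2.39 CPM (SD, n = 4 each).

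Stress-response genes of the endoplasmic reticulum and of amino acid shortage were lower as a group. Of 26 tested unfolded protein and ATF4 response genes, 22 were lower, 3 higher and 1 not called, with the same counts adjusted over the list alone (camera adjusted p = 9.06e-08; adjusted p = 0.210 with an estimated correlation). The chaperone gene DNAJC3 fell from 151 ± 3.33 to 75.6 ± 2.15 CPM (SD, n = 4 each), and asparagine synthetase ASNS (-0.60), the pseudokinase TRIB3 (-0.65) and the cystine transporter SLC7A11 (-0.49) also fell. Of 24 NRF2 antioxidant genes, 8 were higher, 10 lower and 6 not called, also adjusted over the list alone (camera adjusted p = 0.589). NQO1 (-0.65) and TXNRD1 (-0.34) fell and ferritin heavy chain FTH1, which has many pseudogenes, rose (0.76).

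Cell cycle genes were modestly higher. In the list of DNA replication and G1/S, 28 of 32 genes were higher, 2 lower and 2 not called, with the same counts adjusted over the list alone (camera adjusted p = 2.65e-08; adjusted p = 0.210 with an estimated correlation). MCM6, a subunit of the replicative helicase, rose from 157 ± 4.37 to 291 ± 6.12 CPM (SD, n = 4 each), and UHRF1 (0.60) and the histone mRNA binding protein gene SLBP (0.46) rose too. RFC4, a clamp loader subunit, went the other way (-0.71) and lies in the same lower stretch of chromosome 3 as ETV5. In the mitosis and G2/M list, 26 of 36 genes were higher, 2 lower and 8 not called, also adjusted over the list alone (camera adjusted p = 0.00969; adjusted p = 0.525 with an estimated correlation). Its clearest members changed little, as CDC25B (0.31), BUB1 (0.31), PRC1 (0.21) and CCNB1 (0.21). Replication-dependent histone genes, whose mRNAs mostly lack a poly(A) tail, had 3 of 6 higher and 3 not called, with the same counts adjusted over the list alone (camera adjusted p = 0.186), led by HIST1H1C (1.06) and HIST2H2BE (0.72).

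The p53 target list did not pass camera's test (adjusted p = 0.373), while fry called it down (adjusted p = 6.27e-04), with 10 of 29 genes higher, 15 lower and 4 not called, also adjusted over the list alone. GDF15, a secreted stress cytokine, fell from 72.9 ± 3.09 to 12.7 ± 0.536 CPM and TP53INP1 fell (-0.86), while PLK2 (0.71) and C12orf5 (0.75) rose. In the BCL2 family and apoptosis list, 7 of 21 were higher, 9 lower and 5 not called, adjusted over the list alone as well (camera adjusted p = 0.785). The pro-apoptotic genes BMF (-1.38), BBC3 (-0.86) and APAF1 (-0.54) fell and BAX rose (0.46).

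Genes of colon epithelial differentiation were mostly too low to test, at 10 of 30. Of these, 3 were higher, 5 lower and 2 not called, also adjusted over the list alone (camera adjusted p = 0.307). DPP4, a brush border peptidase, fell from 9.41 ± 0.919 to 0.0569 ± 0.0484 CPM (SD, n = 4 each), which was 0 to 2 counts per KO1 library. KLF4 (-0.72) and KRT20 (-0.99) fell and KLF5 rose (0.47). Among 15 eicosanoid enzymes and receptors, 3 were higher, 7 lower and 5 not called, with the same counts adjusted over the list alone (camera adjusted p = 0.745). The phospholipase gene PLA2G4A (-1.08) and the cyclooxygenase gene PTGS1 (-2.14, at only 1.17 ± 0.331 CPM in WT) fell, and PTGES2 (0.34) and PTGER4 (0.68) rose. Of 6 tested cancer-testis antigens, 2 were higher, 3 lower and 1 not called, adjusted over the list alone too (camera adjusted p = 0.690). MAGEA3 rose (0.68) and PRAME fell (-0.28). MAGEA1 had 201 counts over the 4 WT libraries and 1 over the 4 KO1 libraries, a ratio of 205 (95% counting interval 36.3 to 8124). PAGE1 had 134 counts in WT and 0 in KO1, which made it at least 11.3-fold lower against a floor of 3 counts per library. The median of the list was -0.16 with the fitted values and with MAGEA1 and PAGE1 at that floor. Such intervals and floors cover counting error only. The MAGE and PAGE genes have near-identical copies, and their counts are uncertain for that reason.

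Few markers of other cell types could be tested. Of 13 blood cell markers 4 could be tested, of which 3 were lower and 1 was not called. Among the lower were CORO1A (-0.66) and LAPTM5 (-1.37), from 5.82 ± 0.426 and 1.57 ± 0.319 CPM in WT (SD, n = 4 each). CD68 (log2 fold change 0.0041), named after its values were seen, did not pass the test. Of 11 hepatocyte markers 2 could be tested, SERPINA1 (-1.52), which was lower, and TF (0.15, edgeR adjusted p = 0.616). Of 11 squamous epithelium markers 2 could be tested, SFN (0.44), which rose from 179 ± 6.47 to 242 ± 6.61 CPM (SD, n = 4 each), and KRT16 (0.27, edgeR adjusted p = 0.252). In these 3 lists the counts were the same adjusted over the list alone.

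**Figure D3:**
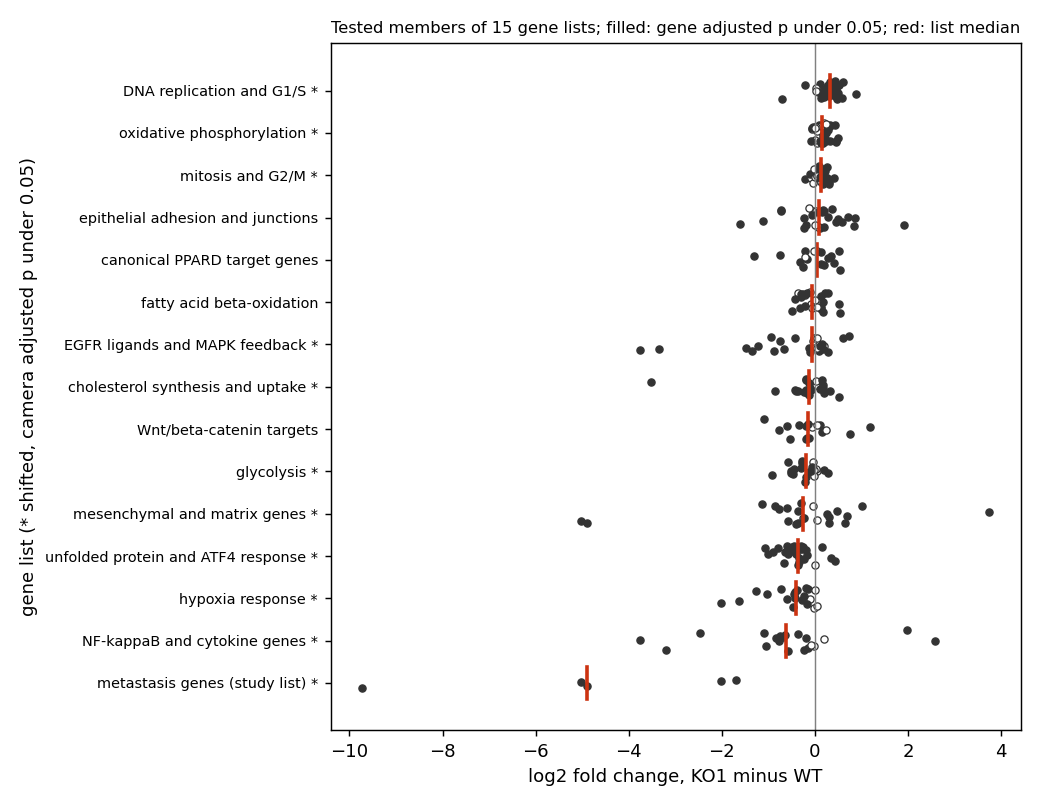
Log2 fold change, KO1 minus WT (x axis), of the tested members (points) of 15 gene lists (y axis), filled where edgeR's adjusted p for the gene was under 0.05, with the list median as a red line and a star at each of the 11 lists that shifted with camera's preset correlation. The medians run from -4.89 for the metastasis list to 0.32 for DNA replication and G1/S.

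In all, 11 of 26 gene lists shifted with camera's preset correlation of 0.01, 3 up and 8 down. With an estimated correlation only the metastasis list, which is not independent evidence, held its call among these 26. Fry called 23 of the 26, all but the lists of beta-oxidation, of PPAR and RXR receptors and of interferon-stimulated genes.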

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

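One library lay far from the other 3 of its group in 10 of 270 groups of 4 values (the named genes and 5 library measures), where chance alone gives about 1 in 20, or 13.5. In WT replicate 3, MVK was 69.0 CPM against 71.7 to 72.0 in the other WT libraries, and CALR was 1066 CPM against 1030.3 to 1035.5. In KO1 replicate 3, ENO1 was 1994 CPM against 2050.1 to 2055 in the other KO1 libraries, and BUB1 was 184 CPM against 168 to 171. The same library had COL6A3 at 0.741 CPM against 0.355 to 0.38, ICAM1 at 0.627 CPM against 0.814 to 0.837, and MAGEA1 at 0.0570 CPM, which was 1 count against 0 in the others. SYTL5 was 52.3 CPM in KO1 replicate 4 against 48.6 to 49.1, CYC1 was 307 CPM in KO1 replicate 1 against 289.8 to 292.6, and EREG was 77.0 CPM in KO1 replicate 2 against 72.5 to 73.0. KO1 replicate 3 held 5 of the 10, and no explanation was tested for that.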

How the results depend on the processing

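The alternative without the genes of 3 shifted chromosome runs and the other running windows were chosen after the data were seen. The real split of the 8 libraries was the only 1 of 35 splits into 4 and 4 with as many changed genes. By edgeR it had 8650, against at most 0 in the other 34 splits (44 to 870 genes there at an unadjusted p under 0.05). Likewise 1 of 35 splits gave as many genes of at least 2-fold (655 against at most 0). Only the real split gave as many shifted lists, 11 against at most 9. The 16 splits that exchange 1 library of each group gave 8 or 9 lists. Each of the other 34 splits mixed WT with KO1 libraries, so the group difference itself added spread there and kept their gene counts low. Those counts are therefore no measure of what chance gives, and no result could rank better than 1 of 35. Since the libraries of a group may be technical replicates, the splits do not bear on chance differences between cultures or lines. With RLE, upper-quartile or no scaling factors, DESeq2, edgeR's exact test, limma-voom, either other filter or the replicate block, the changed genes stayed within 1.5 times 8650, and PPARD stayed lower and past the threshold. Of the values of single named genes, 1287 under these alternatives and without the 3 runs, and 1031 with 1 library left out, with 1 exception, kept their direction and their side of the threshold. Without scaling factors the split was 4941 higher and 3817 lower, with the median of all genes 0.03 higher. With upper-quartile factors it was 3977 higher and 4646 lower, and with RLE factors 4299 and 4341. Which direction held more changed genes therefore depended on the scaling. Without the low-count filter 1096 genes changed at least 2-fold (301 higher, 795 lower) in place of 655, since more low genes were tested. DESeq2 called 659 at least 2-fold, 653 of them shared with edgeR. With an estimated correlation 1 list shifted (0 up, 1 down), with 1 up and 6 down at an unadjusted p under 0.05, and with fry, which does not compare a list with other genes, 23 shifted (5 up, 18 down). The beta-oxidation list changed direction, never past the threshold, without scaling factors (camera adjusted p = 0.937), with CPM of at least 1 in 4 libraries (0.994), with the replicate block (0.966) and without the 3 runs (0.948). Leaving out 1 library in turn gave 8232 to 8455 changed genes, 683 to 708 of at least 2-fold, 11 to 13 lists and a PPARD log2 fold change of -1.08 to -1.03. In those fits the beta-oxidation list, which turned up without WT replicate 1, WT replicate 2 or KO1 replicate 3, had adjusted p-values of 0.913 to 0.9998. The exception among the genes was TF, which was not called and ran from -0.0055 without KO1 replicate 3 to 0.27 without WT replicate 3. The cause of these changes of direction was not tested. Without the 3 runs 8487 genes changed, 613 of at least 2-fold, and 12 lists shifted, the Wnt list being added (0.0491; 2.17e-05 to 0.283 over its alternatives). The number of runs depended on the window: 3 with 51 genes, 5 with 31 genes (on chromosomes 3, 7 and 13 and 2 on 11), and with the widest window tried only the one on chromosome 3, so the 7p and 11q runs were not found there. The median of the 3q run was -0.9996 with 31 genes and -0.99 with the widest window. Equal replicate numbers do not show that samples were paired: the correlations of same-numbered libraries across 10506 genes were 0.17, 0.20, 0.08 and 0.08, although each library correlated best with its own number, a hint from the data and not from the design. The replicate block gave 8988 changed genes, 656 of at least 2-fold (654 shared with the fit without it) and 13 lists, adding the Wnt and epithelial lists (0.0338 each). Depth limits genes at 0 in KO1, where 3 counts amount to 0.157 to 0.178 CPM.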

Other observations

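The tests on fibroblasts, on genes left out of the 3q run and on the number of knockout lines, as well as the rules for a run and for a gene near 0, were chosen after the result was seen. The genes named in this part fall outside the naming rule unless they stand in the report, and were chosen after their values were seen.

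A set of 19 genes was near 0 in KO1 (at most 0.5 CPM) and at least 5 CPM in WT, and 0 genes showed the opposite pattern. Besides UBB, GJA1, COL6A3, MAGEB1, HCLS1, VAT1L and DPP4, the set held TM4SF18 (14.1 ± 1.11 CPM in WT, 0.339 ± 0.217 in KO1), the insulin-like growth factor binding protein gene IGFBP7 (7.03 ± 0.420 and 0.38 ± 0.181), ASB2, BVES, GAS7, KCTD12, MAGEA11, MUC20, SDK2, SNTB1 and UTS2D (SD, n = 4 each). MUC20 and UTS2D lie in the 3q stretch described next. SHROOM2, an actin-binding regulator of cell shape, had 431 counts over the WT libraries and 0 over the KO1 libraries, at least 36.5-fold lower against the floor of 3 counts per library. BVES had 434 counts against 3, a ratio of 147 (95% counting interval 50.1 to 717).

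With a running median of 51 genes, 3 chromosome ends held a stretch with a shifted median, of which only the one on 3q was also found with the widest window tried, while a window of 31 genes gave 5 runs. The last 74 tested genes of 3q, from FAM131A to FAM157A in the order of the GRCh38.p14 gene table, had a median log2 fold change of -0.99, with 72 of 74 below 0 and 70 of these past the threshold. TFRC, the transferrin receptor, fell from 912 ± 13.2 to 435 ± 10.4 CPM (SD, n = 4 each), and the repressor BCL6 (-1.22), the scaffold DLG1 (-1.02), the mitochondrial fusion gene OPA1 (-0.62) and the mucin gene MUC4 (-3.42) fell as well, while HES1 rose (0.73). The 50 tested genes just before that stretch had a median of 0.00069. The first 56 tested genes of 7p, from FAM20C to C7orf26, had a median of -0.45 with 46 below 0, 41 of them past the threshold, but 9 were higher past the threshold, among them ADAP1 (1.00), LFNG (0.90), ACTB (0.75), PRKAR1B (0.39) and PDGFA (0.34). Of the outermost 7 genes of 7p, 6 were above 0, and they belong to the stretch only because the running median takes 1 value over the outermost 25 genes of a chromosome end. The last 31 of 11q, from EI24 to B3GAT1, had a median of 0.31 with 30 above 0, 28 of them past the threshold, CHEK1 (0.30) among them. There too the outermost 25 genes take 1 running median, 0.32, so this stretch reached the minimum of 20 genes for a run only through that rule. These 3 runs held 43 of the 655 genes changed at least 2-fold, all 43 lower, and in the list members of the report they held RFC4, ETV5, EHHADH and EPHB3.

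The run on 3q may reflect a lower DNA copy number of that chromosome end in KO1, a hypothesis that no DNA measurement bears on here. Chance order of the genes was argued against, since the largest running median of 51 genes was 1.03 in size and 1000 shuffles of the genes reached at most 0.253. Trends on transcript length, GC content and expression level were argued against as the whole cause, since the median of the run was -0.99 after they were removed (standard error 0.0421), a correction that moved the other genes by at most 0.155 (95th percentile 0.0946). When the run was set from every other gene, 97.3% of the 37 genes left out were below 0, but these genes had already been seen to be lower, so this does not test a regional cause, and a change of DNA copy number or of chromatin stays open. With 1 knockout line, loss of PPARD and another difference between the line and its parent cannot be told apart as the cause of the runs.

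For the genes near 0, a deletion that takes the neighbours too was argued against for the set, since the median of their 38 nearest tested neighbours was -0.0866 (standard error 0.0486). It could still apply to single genes, since 7 of the 38 neighbours were at least 2-fold lower, among them TRPV2 next to UBB (-2.32) and TM4SF1 next to TM4SF18 (-2.20). The 7 also include MIR570, MUC4, GEMC1 and CCDC50, next to MUC20 or UTS2D in the 3q stretch. The median of that whole stretch was -0.99 and its lower quartile -1.16. MIR570 (-1.51), MUC4 (-3.42), GEMC1 (-1.54) and CCDC50 (-1.93) all lay below that quartile. The shift of the stretch therefore does not account for them in full, and a loss around MUC20 or UTS2D stays open. Fibroblasts mixed into the WT libraries were argued against, since COL1A2 and DCN together reached 0.0589 CPM in WT against 50.6 CPM for COL6A3, although COL1A1, another fibroblast collagen, was 76.7 CPM in WT and still 51.8 CPM in KO1. Silencing of single genes, losses inside them and an effect of PPARD itself stay open and were not tested.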
